A study of Schmidtea mediterranea with 48 samples.

How the data were processed

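RNA was sequenced from whole worms of the planarian Schmidtea mediterranea (clonal line CIW4) after RNA interference (RNAi). Worms were fed bacteria that make double-stranded RNA in liver paste, in 3 feedings, and were sampled on days 6, 12 and 18, per the labels. The double-stranded RNA targeted zfp1, sox8, pax5 or unc22, the last of which is a nematode muscle gene that served as the non-targeting control. Each of the 12 combinations of RNAi and day had 4 replicates, which gave 48 polyA libraries made with the TruSeq kit, per the labels' protocols. The protocol text shared by all samples also mentions sorted cells, but each sample is labelled as whole worm tissue and was treated as such, which the values were not used to check. What a replicate was (separate worms, pools or repeated libraries) is not stated there, so p-values measure only the spread between these libraries, which may be technical in part.

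The deposited values are RPKM (reads per kilobase of feature, scaled to the reads of the library), in 1 table of 28413 features by 48 libraries that the authors made. CASAVA 1.8.2, Bowtie and edgeR are named in the submitters' processing notes, without a role or an order. The reference transcripts, the annotation, any filter on features and the treatment of reads that align to several features are not stated. Features that share sequence with a near-identical copy are therefore uncertain. The table identifies features by SMED30 identifiers and pairs none of them with a gene name, and no reference table was at hand. The targeted genes zfp1, sox8 and pax5 could therefore not be looked up, so the knockdowns and the library labels were not checked on the targets. The lists of cell type markers and pathway genes fixed before the data were examined were not tested for the same reason.

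Whole reads were recovered from the RPKM values by finding each library's factor from exact ratios of low values, and then, for each feature, the largest step of which all 48 values are whole multiples. This worked for 28410 of the 28413 features (largest deviation from a whole number 1.69e-09, tolerance 0.0001). On simulated data of 4470 features the same code gave back 99.96% exactly. Recovered totals ran from 6633481 to 63498231 reads per library (median 22162321). The implied factors between libraries ran from 0.925 to 1.06 and correlated with factors of the trimmed-mean type computed from the recovered reads (r = 0.992, largest difference 0.970%). A floor of 3 reads corresponds to 0.134 RPKM for a feature of the median inferred length (1004 bases) at the median depth, which covers counting error alone. The chi-square per degree of freedom of 72 pairs of replicates, over at least 17706 features with at least 20 reads, ran from 1.61 to 13.0, so no replicate was a copy or a re-division of another's reads.

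Features with a mean RPKM of at least 0.5 over the 48 libraries were tested, which left 22667 (79.8%). The values were put on a log2 scale after a pseudocount of 0.5 was added, which understates the fold changes of low features. The test was limma's moderated test (limma 3.58.1 in R 4.3.3) with 1 mean per group, all 12 groups in a single model, and the trend and robust options. P-values are two-sided and were adjusted by the Benjamini-Hochberg method within each contrast. A feature is described as called, or as having risen or fallen, where its adjusted p was under 0.05. The contrasts were each knockdown against unc22 on each day, the difference of each knockdown effect between day 18 and day 6, the knockdowns against each other on day 18, and unc22 on days 12 and 18 against day 6. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work.

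The named features follow a rule fixed before the data were examined: per contrast, the 2 called features with the largest rise and the 2 with the largest fall. They had a mean of at least 1 RPKM in the higher group and, except for differences between days, no overlap between the libraries of both groups. The planned longer lists of named genes needed gene names and were not used. Groups of features that behaved alike (for example those that fell at least 2-fold on all 3 days) were defined after the data were seen. Percentages of summed RPKM are sums over such a group divided by the sum over the table. Overlaps between knockdowns on the same day share control libraries. They are given with the value from simulated unchanged groups, the product expected of independent lists per direction, and the value after the 4 controls were split into 2 and 2.

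The test was checked on data simulated from the real means and depths for each of the 9 knockdown contrasts, with 22664 features, a dispersion of 0.02, and 67 features changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. Of the features changed 1.5-fold, 31.3% to 44.8% were recovered, depending on the contrast. For a 2-fold change this share was 82.1% to 89.6%, and 2.67% to 9.52% of calls were false. The simulated features were independent, with 1 dispersion and no component shared by libraries, so these shares may not hold for the real libraries. Replicate numbers were not used to pair libraries. The alternatives fixed before the data were examined were the pseudocount (0.1 and 1), the filter (none, or a mean RPKM of at least 2), median ratio scaling, quantile normalization, a fit of only the groups compared, a replicate block, plain eBayes, stricter thresholds, split controls, and leaving out each library in turn. Chosen after seeing the data were voom on the recovered reads, cyclic loess, library weights, leaving out libraries far along a shared component, and thinning all libraries to 6633481 reads.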

Results

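Polyadenylated RNA of whole planarians was measured after RNAi against zfp1, sox8 or pax5, with unc22 as the non-targeting control. Each RNAi was sampled on days 6, 12 and 18 with 4 libraries per group, so 12 groups and 48 libraries were compared. Recovered depth ran from 6633481 to 63498231 reads per library, with a median of 22162321. The sox8 day 6 group held the shallowest library (group range 6633481 to 25584978) and the pax5 day 6 group the deepest (22527386 to 63498231). The table does not pair its identifiers with gene names, so the levels of zfp1, sox8 and pax5 themselves are not reported and features are named by identifier. Values are RPKM, and changes are on the scale of log2(RPKM + 0.5) with limma's standard error (SE).

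RNAi against zfp1, a zinc finger gene of planarian stem cells that the epidermal lineage needs, was followed by falls in more features on each later day of sampling. Features that changed at least 2-fold against unc22 numbered 13 on day 6, 253 on day 12 and 607 on day 18, and 8, 237 and 509 of them fell. On day 6 the largest fall was that of SMED30023708, from 17.2 ± 1.02 RPKM in unc22 to 4.56 ± 0.576 in zfp1 libraries (SD, n = 4). On day 12 SMED30020396 fell from 384 ± 17.5 to 15.2 ± 9.72 RPKM (SD, n = 4), and SMED30035904, at 315 ± 15.9 RPKM in unc22, fell most on the log2 scale. On day 18 SMED30023017 fell from 196 ± 16.2 to 4.51 ± 3.83 RPKM (SD, n = 4) and SMED30032042 from 558 ± 48.3 to 17.3 ± 12.9 RPKM.

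The changes in log2 were -1.81 for SMED30023708 (SE 0.07, adjusted p = 6.70e-23), -4.90 for SMED30035904 (SE 0.27, adjusted p = 7.83e-18) and -5.60 for SMED30023017 (SE 0.25, adjusted p = 3.47e-21). Not every fall deepened with time: that of SMED30023708 was -1.66 on day 12 and -1.11 on day 18. SMED30008505 changed by -1.47 in log2 units on day 6 and by -3.81 on day 18. It stood at 1.29 and 1.28 RPKM in zfp1 libraries on days 12 and 18. The largest rises were 1.29 for SMED30002872 and 1.20 for SMED30000949 on day 6, and 1.36 for SMED30003487 and 1.33 for SMED30033583 on day 12, in log2 units. On day 18 SMED30004187 rose by 4.42 (SE 0.56, adjusted p = 2.28e-08), from 5.22 ± 2.62 to 131 ± 98.8 RPKM (SD, n = 4), and SMED30029247 rose by 3.63, from 17.9 ± 6.59 to 236 ± 126 RPKM. With any change counted, limma called 308 features on day 6 (165 higher, 143 lower), 2979 on day 12 (1135 higher, 1844 lower) and 5449 on day 18 (2162 higher, 3287 lower). Under quantile normalization the split turned to 2020 higher and 1720 lower on day 12, and to 3841 higher and 2857 lower on day 18. The day 6 split turned to 214 higher and 238 lower under quantile normalization, 194 and 247 under cyclic loess, 205 and 216 with library weights, 39 and 53 in a fit of only the groups compared, and 93 and 152 without the libraries over 2 SD on a component shared by libraries. It was 164 and 166 with median ratio scaling, so no direction prevailed on day 6. The day 6 count was 192 without zfp1 replicate 4, 92 in a fit of only the groups compared, 146 at equal depth and 490 with voom, and the day 12 count was 1525 at equal depth.

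**Figure D1:**
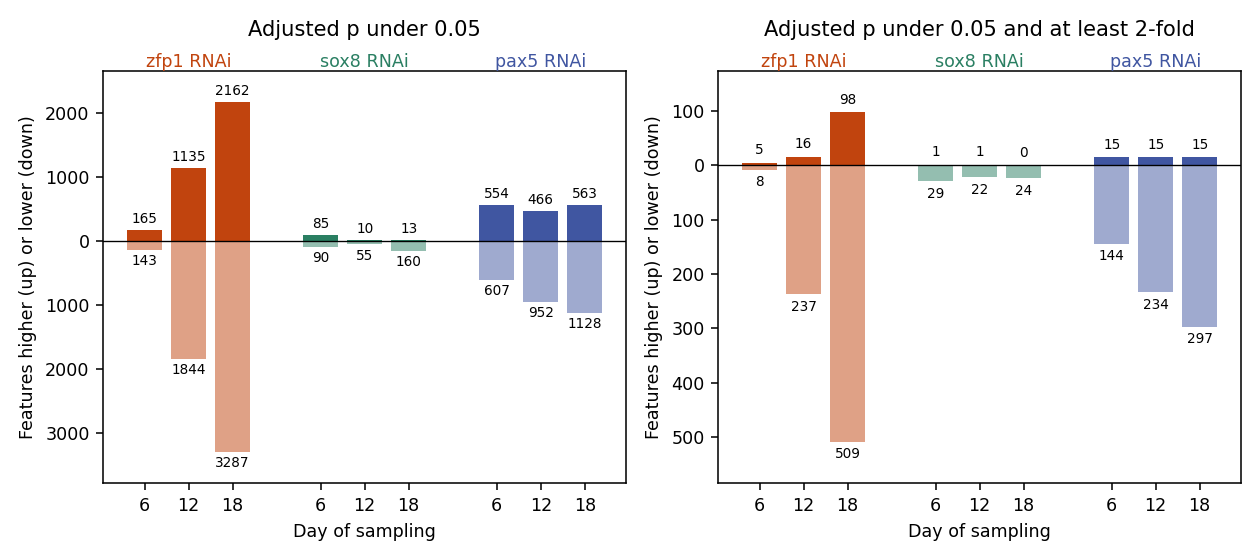
Number of features called higher (up) or lower (down) than unc22 on each day, for each knockdown, at any size (left) and at a change of at least 2-fold (right). The zfp1 bars lengthened from 8 to 237 to 509 falls of at least 2-fold, while sox8 had 29, 22 and 24 such falls and pax5 had 144, 234 and 297.

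Groups of features defined after the data were seen separate early from late falls after zfp1 RNAi. A group of 229 features first fell at least 2-fold on day 12, with median log2 changes of -0.24, -1.44 and -1.88 on days 6, 12 and 18. Their share of summed RPKM on day 18 was 2.57 ± 0.0449% in unc22 and 0.454 ± 0.0629% in zfp1 libraries (SD, n = 4). Another 295 features first fell at least 2-fold on day 18, with medians of -0.02, -0.49 and -1.22, and 213 of them were already called lower on day 12. In the sox8 day 18 libraries the medians of these groups were -0.41 and -0.10, and 93 of the 229 and 16 of the 295 features were called lower. In the pax5 day 18 libraries the medians were -0.58 and -0.21, and 133 of the 229 and 118 of the 295 were called lower. Only 8 features had fallen at least 2-fold on day 6, and all 8 were called lower on day 18 as well. Of the 143 features called lower on day 6, 118 were also lower on day 12, against 11.6 expected of independent lists; each day has its own control libraries.

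The zfp1 effect itself was compared between day 18 and day 6, which asks whether the response was still building. It was more negative on day 18 in 2356 features and more positive in 1056 (3412 called by limma), and in 501 and 106 of these the difference was at least 2-fold. SMED30023017 led with a difference of -5.24 (SE 0.35, adjusted p = 5.58e-15), followed by SMED30032042 with -5.02. SMED30004187 moved the other way by 4.48 (SE 0.79, adjusted p = 2.82e-05) and SMED30029247 by 3.71. Under quantile normalization the split was 2025 more positive and 2094 more negative. At equal depth the count was 2233, and SMED30004187 was not called with voom (adjusted p = 0.122; range over all alternatives 4.39e-06 to 0.122).

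RNAi against sox8, a SoxE-family transcription factor gene, gave the narrowest response on days 12 and 18, and on all days its changes of at least 2-fold were almost wholly falls. Such falls numbered 29 on day 6, 22 on day 12 and 24 on day 18, against 1, 1 and 0 rises. The day 6 number was 22 under quantile normalization and 21 under cyclic loess, so its excess over the later days depended on the scaling. SMED30025741 fell from 474 ± 25.5 RPKM in unc22 to 12.4 ± 1.71 in sox8 libraries on day 12, and from 425 ± 5.53 to 10.2 ± 4.60 on day 18 (SD, n = 4). SMED30031990 fell from 286 ± 20.8 to 14.2 ± 5.16 RPKM on day 6 and from 155 ± 6.62 to 3.44 ± 1.10 on day 18. A set of 20 features, defined after the data were seen, fell at least 2-fold on all 3 days, with medians of -2.87, -2.97 and -3.21. Their share of summed RPKM on day 6 was 1.01 ± 0.0434% in unc22 and 0.0900 ± 0.0187% in sox8 libraries (SD, n = 4), and on day 18 it was 0.499 ± 0.0161% against 0.0349 ± 0.00332%.

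SMED30008921 fell by 4.40 in log2 units on day 6 (SE 0.30, adjusted p = 2.60e-14), and SMED30025741 fell by 5.40 on day 18 (SE 0.27, adjusted p = 5.29e-18). The largest rises, such as 1.09 for SMED30019921 on day 12, were small and several depended on single libraries. On day 6, SMED30002813 rose by 1.61 and SMED30030302 by 0.88 (adjusted p = 0.0155 and 0.0269). Without sox8 replicate 3 neither was called (adjusted p = 0.0897 and 0.165), nor without unc22 replicate 1 (0.0664 and 0.0994) or unc22 replicate 2 (0.0811 and 0.0874), and SMED30030302 was not called without sox8 replicate 1 (0.0589). On day 12 SMED30011585 rose by 0.77 but was not called without unc22 replicate 3 (adjusted p = 0.0518). On day 18 SMED30017561 rose by 0.80, and SMED30019921 rose by 0.89 but was not called without sox8 replicate 4 (adjusted p = 0.0746). At equal depth SMED30017561 was not called (adjusted p = 0.449), nor was SMED30019921 on days 12 and 18 (0.609 and 0.519). SMED30011585 on day 12 (0.52) and SMED30030302 on day 6 (0.0715) were not called there either. In a fit of only the groups compared, SMED30011585 was not called (0.0818).

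At any size limma called 175 features for sox8 on day 6 (85 higher, 90 lower), 65 on day 12 (10 higher, 55 lower) and 173 on day 18 (13 higher, 160 lower). The day 6 count rested on single libraries: it was 82, 381, 43 and 1144 without sox8 replicates 1, 2, 3 and 4, and 53, 46, 55 and 431 without unc22 replicates 1, 2, 3 and 4. On day 6 the split was 31 higher and 68 lower under quantile normalization and 21 higher and 71 lower under cyclic loess, but 152 and 119 with voom and 105 and 67 with a mean RPKM of at least 2. The count was 32 in a fit of only the groups compared (6 higher, 26 lower), 42 at equal depth, 271 with voom and 499 with library weights. The day 12 count was 43 without unc22 replicate 2, 26 at equal depth, 137 in a fit of only the groups compared and 134 with library weights. The day 18 count was 115 without sox8 replicate 4 and 101 at equal depth.

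Between day 6 and day 18 the sox8 effect differed in 7 features by limma (4 more positive, 3 more negative), while 1850 features had an unadjusted p under 0.05. The named ones were SMED30023556 and SMED30035247, which moved up by 1.52 and 1.35, and SMED30032413 and SMED30006798, which fell by 1.04 and 0.59 in log2 units. SMED30035247 stood at 0.0284 RPKM in sox8 libraries on day 6 and 0.0588 on day 18, with at most 1 read per library (3 reads are 0.206 RPKM at its length), while unc22 went from 1.36 to 0.274 RPKM, so its difference is a fall in the control. SMED30023556 had at most 4 reads in the sox8 day 6 libraries (mean 0.276 RPKM, under the 0.412 RPKM of 3 reads at its length) and 3 to 8 on day 18 (mean 0.906), while unc22 went from 1.09 to 0.539 RPKM, so its difference rests on few reads and in part on the control. SMED30032413 and SMED30006798 rose in unc22 from 0.733 to 1.64 and from 52.8 to 77.3 RPKM between these days and changed less in sox8 libraries (1.09 to 0.863 and 65.4 to 63.4 RPKM). SMED30023556, SMED30035247, SMED30032413 and SMED30006798 were not called in 15, 5, 14 and 14 of the alternatives tried, in that order. The count of calls was 4, 3 and 13 without sox8 day 6 replicates 1, 2 and 4, 3, 1 and 0 without sox8 day 18 replicates 1, 2 and 4, 3, 2 and 15 without unc22 day 6 replicates 1, 2 and 4, and 1 without unc22 day 18 replicate 4. It was 31 with voom (4 more positive, 27 more negative), 15 under quantile normalization (6 and 9), 14 under cyclic loess (6 and 8) and 0 at equal depth.

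RNAi against pax5, a paired box transcription factor gene, gave a response that was broad from day 6 and, at sizes of at least 2-fold, consisted mostly of falls. Features that fell at least 2-fold against unc22 numbered 144 on day 6, 234 on day 12 and 297 on day 18, against 15 rises on each day. SMED30008921 had the largest fall of day 6 on the log2 scale, to 0.815 ± 0.679 RPKM from 60.4 ± 3.58 in unc22 (SD, n = 4). SMED30003024 fell from 165 ± 5.60 to 1.06 ± 0.369 RPKM on day 18, and SMED30035904 from 301 ± 5.08 to 2.44 ± 0.257 RPKM (SD, n = 4). The 144 features that fell at least 2-fold on day 6, a group defined after the data were seen, had medians of -1.56, -2.11 and -2.21 on days 6, 12 and 18. Their share of summed RPKM on day 6 was 1.04 ± 0.0250% in unc22 and 0.335 ± 0.00961% in pax5 libraries (SD, n = 4), and 142 of them were still called lower on day 18.

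The change of SMED30003024 on day 18 was -6.76 (SE 0.15, adjusted p = 5.27e-33) and that of SMED30035904 was -6.69 (SE 0.27, adjusted p = 9.18e-23). On day 12 SMED30020396 fell by 5.90 and SMED30035904 by 5.88. Rises were led by SMED30022734 on day 6 (2.68, SE 0.36, adjusted p = 6.62e-07), SMED30033800 on day 12 (2.80, SE 0.27, adjusted p = 8.21e-11) and SMED30034302 on day 18 (2.76, SE 0.24, adjusted p = 2.45e-12). SMED30033800 rose by 1.95 on day 18. SMED30022734 rose by 2.38 on day 12 but was not called with voom (adjusted p = 0.0565; range over all alternatives 2.32e-07 to 0.0565). Limma called 1161 features on day 6 (554 higher, 607 lower), 1418 on day 12 (466 higher, 952 lower) and 1691 on day 18 (563 higher, 1128 lower). At any size the day 6 split depended on the processing: it was 368 higher and 748 lower under cyclic loess and 262 and 627 without the libraries over 2 SD, but 862 and 865 with voom, 638 and 565 with a mean RPKM of at least 2, and 1227 and 958 with library weights. The day 12 split was 952 higher and 1054 lower in a fit of only the groups compared and 1111 and 1334 with library weights, and that on day 18 was 853 and 1072 under quantile normalization and 1077 and 1348 with library weights. Library weights raised the counts of days 6 and 12 to 2185 and 2445, and equal depth lowered those of days 6 and 18 to 723 and 1096.

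From day 6 to day 18 the pax5 effect became more negative in 403 features and more positive in 49 (452 called by limma). SMED30020726 showed the largest difference, at -3.59 (SE 0.16, adjusted p = 2.21e-20), and SMED30003024 followed with -3.33. The effect on SMED30018762 was more positive by 2.06 on day 18. Its level in unc22 was 41.5 ± 6.59 RPKM on day 6 and 2.96 ± 0.370 on day 18 (SD, n = 4), and in pax5 libraries it went from a mean of 11.4 to 3.61 RPKM. It rose in neither, and the difference comes from the larger fall in the control. SMED30034302 moved up by 1.41 but was not called with a pseudocount of 0.1 (adjusted p = 0.560), with voom (0.342) or at equal depth (0.0929); over all alternatives its adjusted p ran from 0.000194 to 0.560. The split was 119 more positive and 396 more negative under quantile normalization and 125 and 439 under cyclic loess, and library weights gave 702 calls.

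**Figure D2:**
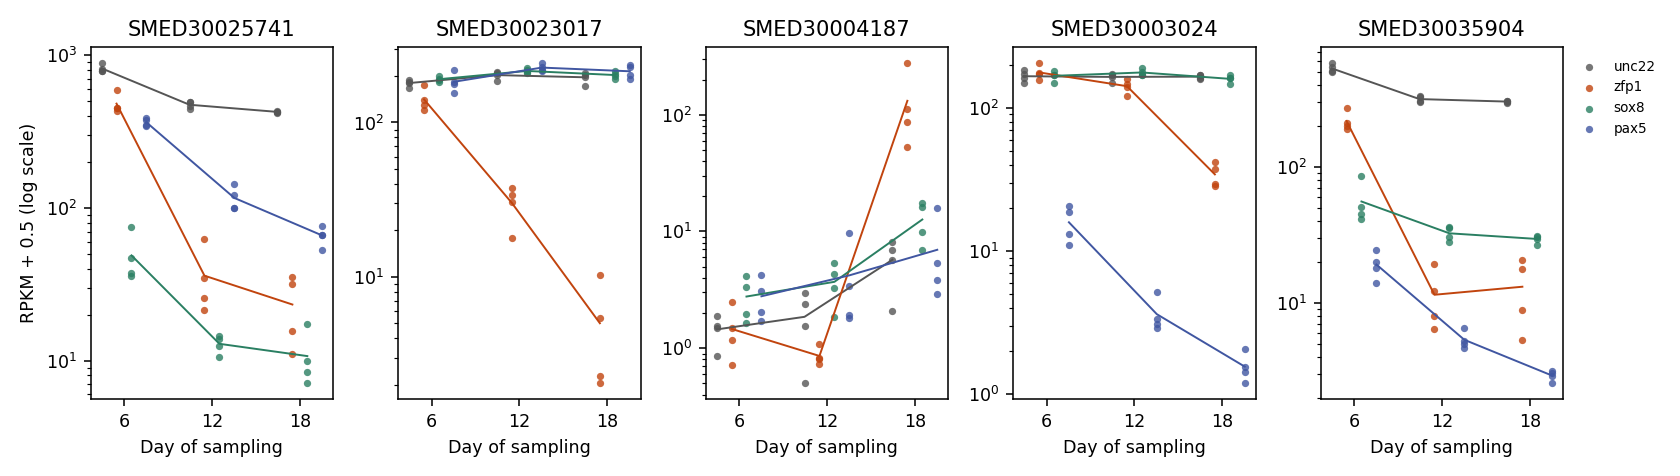
RPKM + 0.5 (log axis) of 5 named features in each library by day of sampling, with lines through the group means of RPKM, for the 4 RNAi groups. SMED30025741 fell most in sox8 libraries on all 3 days. In pax5 libraries it changed by -1.18, -2.04 and -2.70 in log2 units, less than in zfp1 libraries on days 12 and 18. On day 6 it stood at 363 RPKM in pax5 and 482 in zfp1 libraries, against 821 in unc22. SMED30023017 fell in zfp1 libraries alone (4.51 RPKM on day 18 against 196 in unc22), SMED30003024 fell most in pax5 libraries, and SMED30004187 rose in the 4 zfp1 libraries of day 18.

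The knockdowns were compared with each other to ask which falls are shared. All 20 features that fell in sox8 on all 3 days were called lower in zfp1 on days 12 and 18, with medians of -3.63 and -3.47, while on day 6 the zfp1 median was -0.78 and 9 of the 20 were called. In pax5 libraries the same features parted: 13 were called lower and 3 higher on day 18, with a median of -1.80. SMED30009302, for example, changed by -3.49 in sox8 and -3.52 in zfp1 on day 18 but by 0.17 in pax5 (not called), whereas SMED30035904 fell in all of them, with changes of -3.35 in sox8, -4.71 in zfp1 and -6.69 in pax5. With sox8 features chosen against controls 1 and 2 (20 features), their zfp1 medians against controls 3 and 4 were -3.59 on day 12 and -3.42 on day 18. On day 18, 15 features fell at least 2-fold in all 3 knockdowns, 106 in zfp1 and pax5, 8 in zfp1 and sox8 and 0 in sox8 and pax5, while 380 did so in zfp1 alone, 176 in pax5 alone and 1 in sox8 alone. These last counts compare thresholds and do not test differences between knockdowns.

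Same-direction calls in zfp1 and pax5 on day 18 numbered 899 (147 higher, 752 lower), and 217 features went opposite ways. Independent lists of these sizes would share 53.7 higher and 164 lower, and no such value was computed for the opposite ways. Splitting the controls gave 630 and 599, against 128 and 127 expected of independent lists in both directions together. Simulated unchanged groups shared 0, but features without an effect are rarely called, so this 0 does not measure what shared controls add. The covariance of the zfp1 and pax5 log2 changes was 0.0501, against 0.0107 in the simulation. Their correlation was 0.388, below the 0.469 that shared controls alone gave in the simulation, and 0.298 and 0.275 with split controls. For zfp1 and sox8 on day 18 the overlap was 145 (139 lower, against 23.2 expected), 66 and 80 with split controls, with a covariance of 0.0307 and a correlation of 0.400 (0.242 and 0.221 with split controls). For sox8 and pax5 it was 123 (113 lower, against 7.96 expected), 62 and 56 with split controls, with a covariance of 0.0258 and a correlation of 0.401 (0.214 and 0.201). The simulated values are the same for these pairs. Correlations cannot be set against the simulated one to measure a shared effect, because real effects change the spread they are divided by, and features are not independent replicates.

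**Figure D3:**
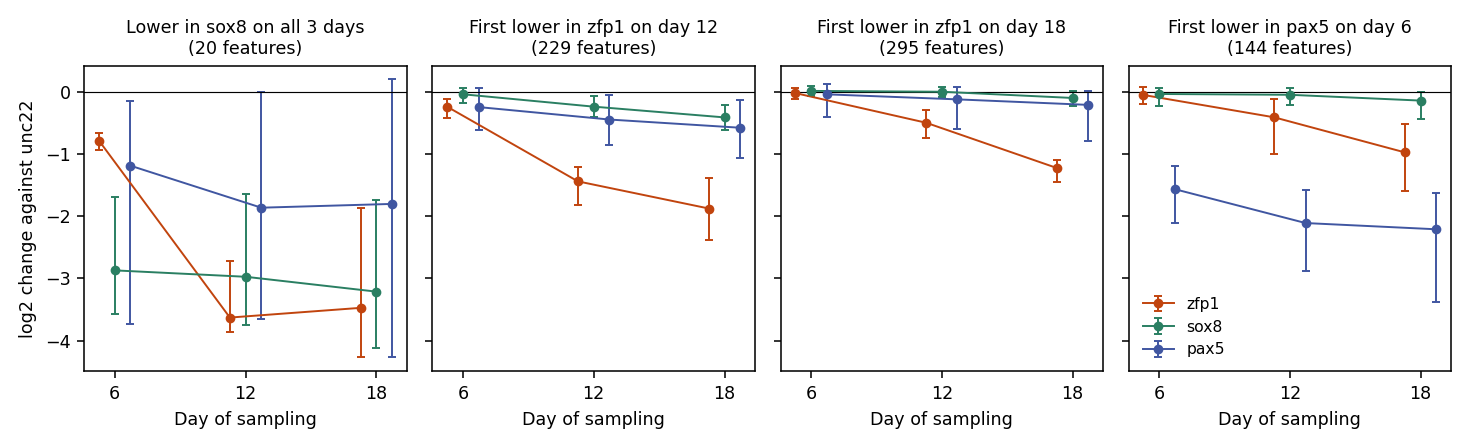
Median log2 change against unc22 on each day for each knockdown in 4 groups of features defined after the data were seen, with bars from the lower to the upper quartile over features. The 20 features chosen for falling in sox8 on all 3 days had zfp1 medians of -0.78, -3.63 and -3.47, and the 144 features chosen for falling first on day 6 in pax5 had zfp1 medians of -0.05, -0.41 and -0.97.

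Direct contrasts on day 18 tested the differences between knockdowns. zfp1 libraries were lower than sox8 libraries in 3286 features and higher in 1911, by at least 2-fold in 420 and 105. Against pax5 libraries they were lower in 3239 and higher in 2175, by at least 2-fold in 393 and 235. SMED30023017 was lowest in zfp1, at 4.51 ± 3.83 RPKM against 202 ± 10.8 in sox8 (SD, n = 4) and a mean of 214 in pax5, and SMED30032042 differed by -5.40 and -5.43 in log2 units. On the other side, SMED30006763 was higher in zfp1 than in pax5 by 5.17 (SE 0.16, adjusted p = 1.16e-27) and SMED30007443 followed, with 204 ± 41.5 and 45.0 ± 7.65 RPKM in zfp1 against 5.17 ± 0.979 and 0.915 ± 0.223 in pax5. SMED30003738 was higher in zfp1 than in sox8 by 3.66, and SMED30007501 by 3.60, the latter with 1 zfp1 library at 366 RPKM and the others between 27.3 and 34.3. Under quantile normalization the splits became 3245 higher and 2812 lower against sox8, and 3139 higher and 2832 lower against pax5.

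Of the features that fell at least 2-fold in zfp1 on day 18, 403 were also called lower than in both other knockdowns, with a zfp1 median of -1.43. The matching numbers were 206 for pax5, with a median of -1.94, and 3 for sox8, with a median of -5.34. sox8 libraries were higher than pax5 libraries in 921 features and lower in 417 (867 calls in all at equal depth), by at least 2-fold in 243 and 29. SMED30003024 stood at 159 ± 8.73 RPKM in sox8 and 1.06 ± 0.369 in pax5 (SD, n = 4), a difference of 6.70 (SE 0.15, adjusted p = 7.21e-33), and SMED30023073 differed by 4.92. SMED30009302 and SMED30014876 were lower in sox8 than in pax5, with differences of -3.66 (SE 0.17) and -3.43 (SE 0.23).

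**Figure D4:**
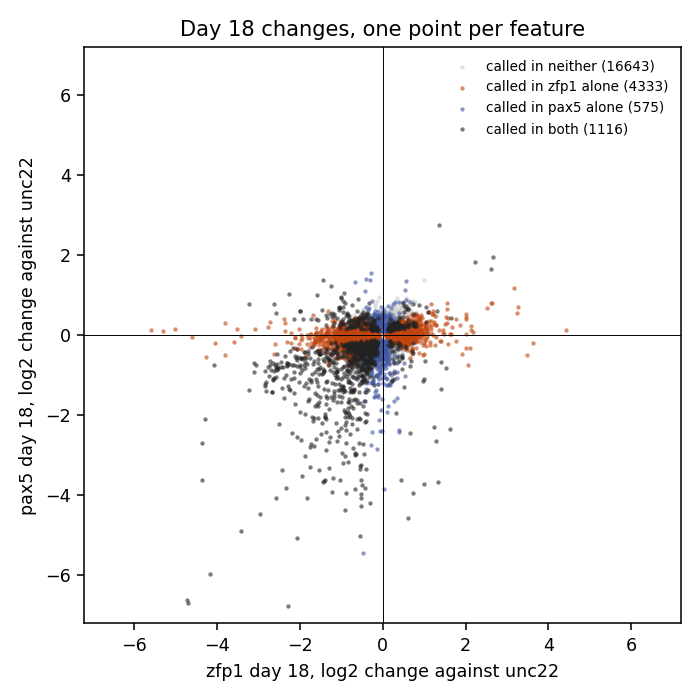
Log2 change against unc22 on day 18 in zfp1 (horizontal) and in pax5 (vertical), 1 point per tested feature, with colours for where it was called. The 1116 features called in both comparisons lie mostly at the lower left, and the 4333 called in zfp1 alone spread along the horizontal axis.

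Control worms changed with time as well, which sets the background for the day by day comparisons. Between day 6 and day 18, unc22 libraries rose in 4828 features and fell in 3849 (8677 called by limma, 5485 at equal depth; 4376 and 4583 under cyclic loess), but by at least 2-fold in 79 and 164 alone. By day 12, 4074 features were called (2413 higher, 1661 lower; 2266 at equal depth), and cyclic loess gave 2229 higher and 2287 lower, so the excess of rises over falls in the control depended on the scaling. SMED30005982 fell from 39.5 ± 3.32 RPKM on day 6 to 2.58 ± 0.414 on day 12 (SD, n = 4), and SMED30018762 fell by 3.70 in log2 units to day 12. SMED30035485 fell by 4.06 to day 18. SMED30015328 rose from 22.2 ± 3.36 to 104 ± 4.77 RPKM on day 12, and SMED30022734 from 1.37 ± 0.614 to 27.4 ± 5.20 RPKM on day 18 (SD, n = 4). SMED30023781 rose by 1.89 to day 12 and SMED30029247 by 2.53 to day 18. Of the 20 features that fell in sox8 on all 3 days, 14 were called lower in unc22 on day 18 than on day 6, with a median of -0.77.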

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

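The tests against feature length and against shared reads were chosen after the results they concern had been seen. Features were called differently on day 18 and day 6 by limma's test of the difference itself, which is why the following results are listed. The zfp1 effect differed in 3412 features, among them SMED30023017 (-5.24), SMED30032042 (-5.02), SMED30004187 (4.48) and SMED30029247 (3.71), in log2 units. The pax5 effect differed in 452 features, among them SMED30020726 (-3.59), SMED30003024 (-3.33), SMED30018762 (2.06) and SMED30034302 (1.41). The sox8 effect differed in 7 features, among them SMED30032413 (-1.04), SMED30006798 (-0.59), SMED30023556 (1.52) and SMED30035247 (1.35).

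Other results are listed because 1 library of a group of 4 lay far from the rest by Dixon's test, which happens by chance in about 1 of 20 groups. Of 113 groups tested for named features, 5 met it, which is no more than chance gives. SMED30007501 stood at 366 RPKM in zfp1 day 18 replicate 3 and at 27.3 to 34.3 in the others, a gap of 0.979 of the whole range. SMED30031990 stood at 21.9 RPKM in sox8 day 6 replicate 3 and at 11.3 to 11.9 in the others (0.946 of the range). In pax5 day 18 libraries SMED30018762 stood at 4.68 RPKM in replicate 3 and 3.19 to 3.30 in the others (0.929), SMED30020726 at 8.01 in replicate 4 and 7.15 to 7.21 in the others (0.927), and SMED30023073 at 1.49 in replicate 1 and 0.754 to 0.837 in the others (0.887). Of 24 groups tested for values per library, 1 met it. The score of pax5 day 18 replicate 4 on the component described next was -5.33, and those of the others were 1.15 to 2.24 (0.856 of the range).

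Libraries departed from their group means along 1 shared component, which held 9.95% of the residual variance (the next held 5.98%) and was widest on day 6, with an SD of scores of 12.8, against 3.97 on day 12 and 7.92 on day 18. The scores of zfp1 day 6 replicate 1 (28.3) and pax5 day 6 replicate 3 (19.1) were the highest. After cyclic loess the first component held 7.12%, and whether it was the same component is not reported here. The share did not fall as far as the bound set beforehand. The next component already held 5.98%, so even full removal of the first could hardly have met that bound. This test therefore does not decide on an abundance trend. The loadings before loess correlated with mean abundance across features (rho = 0.569), although features are not independent replicates. A rho of 0.034 with feature length argues against length. Depth cannot be told apart, because its correlation with the scores over 48 libraries lay between the bounds set beforehand (rho = -0.255, permutation p = 0.0796; r = -0.265, p = 0.0679, and -0.200 without the 2 farthest libraries). No biological explanation was tested, since the sample labels used here separate the libraries of a group by replicate number alone. A component within groups may be biological or technical.

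Features that fell in sox8 on all 3 days also fell in zfp1 on days 12 and 18, and both the set and the overlap were found in these data. Shared control libraries do not account for it, since the zfp1 day 12 median of the features chosen with controls 1 and 2 was -3.59 against controls 3 and 4. Reads shared between near-identical features cannot be told apart from separate falls. In pax5 the day 18 changes of the set spread over 11.4 times their median SE, which excludes only that all 20 copy a single sequence, while several families of copies stay possible. A candidate explanation is that both knockdowns deplete the same cells, to a smaller extent on day 6 after zfp1 RNAi. It stays untested, because no marker could be matched to an identifier.

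The zfp1 response grew from day 6 to day 18. Thinned to equal depth, day 18 still had 3857 calls against 146 on day 6, a ratio of 26.4, which argues against depth. In the 501 features that differed downward by at least 2-fold, zfp1 libraries changed by a median of -1.29 between the days (quartiles -1.95 and -0.90) and unc22 libraries by 0.09. This argues against a drift of the control as the main source in these features as a set. In unc22, 145 of the 501 were called higher and 105 lower on day 18 than on day 6, so the control may contribute in single features. Features that differed upward were not examined in this way. What stays open is a biological course, such as a progressive loss of cells that are no longer replaced, which may fit these values but was not tested.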

How the results depend on the processing

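Chosen after seeing the data were voom on the recovered reads, cyclic loess, library weights, the fit without the 2 libraries scoring over 2 SD on the shared component, and thinning to equal depth; the other alternatives were planned. Without the leave-one-out fits, 224 counts of calls stayed within 1.5 times their value and 75 did not. Leaving out 1 library kept 139 counts within that bound and moved 21. No named feature reversed its direction, and 13 of the 68 named results were not called in at least 1 alternative (36 of their values under other settings and 40 with 1 library left out, against 1046 and 600 that stayed called). Depth limits small changes: at 6633481 reads per library most counts fell, which the loss of reads explains by construction. For every other change the cause was not tested. The planned gene list tests, their estimated correlation and the look-up of the targeted genes were not run, because identifiers are not paired with names.

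The replicate block moved no count of calls by over 1.5 times and kept between 85.7% and 100% of the calls, although 1 named result, SMED30023556 in the sox8 difference between days, was not called under it (adjusted p = 0.0553; range over its alternatives 0.0133 to 0.681). Replicate numbers do not pair the libraries by the deviations from group means: the mean correlation was -0.00421 for the same number and 0.00174 for different numbers, and 9 of 48 libraries correlated best with their own number. With the replicate block, zfp1 day 18 against unc22 day 18 had 5398 calls, pax5 day 18 against unc22 day 18 had 1654 and sox8 day 18 against unc22 day 18 had 161.

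A requirement of at least 2-fold lowered every count, since it removes small changes by construction: zfp1 13, 253 and 607, sox8 30, 23 and 24, and pax5 159, 249 and 312 on days 6, 12 and 18, differences between days 607 (zfp1), 3 (sox8) and 103 (pax5), 525 for zfp1 against sox8, 628 for zfp1 against pax5, 272 for sox8 against pax5, and 57 and 243 for unc22 on days 12 and 18. At an adjusted p under 0.01 limma called 142 and 1798 for zfp1 on days 6 and 12, 41, 43 and 108 for sox8, 683 and 933 for pax5 on days 6 and 12, 2368 for unc22 on day 12, and 0 for the sox8 difference between days, where 1850 features had an unadjusted p under 0.05 and voom called 31 at 0.05.

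The sox8 difference between days, 7 in the reported fit, was 4 with a mean RPKM of at least 2, 15 under quantile normalization, 16 in a fit of only its groups, 31 with voom, 14 under cyclic loess, 14 with library weights, 15 without the libraries over 2 SD, and 0 at equal depth (1510 features at an unadjusted p under 0.05). The sox8 day 6 count of 175 was 99 under quantile normalization, 32 in a fit of only its groups, 271 with voom, 92 under cyclic loess, 499 with library weights, and 526 without the libraries over 2 SD. The sox8 day 12 count of 65 was 137 in a fit of only its groups and 134 with library weights. The zfp1 day 6 count of 308 was 92 in a fit of only its groups and 490 with voom. Library weights gave 2185 and 2445 for pax5 on days 6 and 12 and 702 for its difference between days.

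At equal depth the counts were 146 and 1525 for zfp1 on days 6 and 12, 42, 26 and 101 for sox8, 723 and 1096 for pax5 on days 6 and 18, 2233 for the zfp1 difference between days, 867 for sox8 against pax5, and 2266 and 5485 for unc22 on days 12 and 18. With the controls split both ways, overlaps in the same direction fell to 5 and 7 (zfp1 and sox8), 14 and 15 (zfp1 and pax5) and 14 and 15 (sox8 and pax5) on day 6, to 28 and 28, 241 and 257, and 17 and 18 on day 12, and to 66 and 80, 599 in 1 of both splits, and 62 and 56 on day 18. Fewer control libraries enter each comparison there, and no control is shared.

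Leaving out 1 library gave 192 to 377 calls for zfp1 on day 6, 2370 to 2826 on day 12 and 4863 to 5149 on day 18. For sox8 the ranges were 43 to 1144, 43 to 59 and 115 to 155, and for pax5 847 to 1316, 1080 to 1319 and 1376 to 1561. Differences between days ranged from 3147 to 3542 (zfp1), 0 to 15 (sox8) and 380 to 458 (pax5). Knockdowns against each other ranged from 4598 to 5021 (zfp1 and sox8), 4897 to 5222 (zfp1 and pax5) and 1133 to 1243 (sox8 and pax5), and unc22 from 3051 to 3806 on day 12 and 7479 to 8152 on day 18. The lows came without zfp1 day 6 replicate 4 (192), sox8 day 6 replicate 3 (43), unc22 day 12 replicate 2 (43) and sox8 day 18 replicate 4 (115, and 0 for the difference between days, with 1617 features at an unadjusted p under 0.05), and the highs of 1144 and 15 without sox8 day 6 replicate 4 and unc22 day 6 replicate 4. Each of the 8 libraries moved the sox8 day 6 count by over 1.5 times, and 10 of 16 moved the sox8 difference between days.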

Other observations

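All groups of features in this part were chosen after the data were seen, and the counts of splits were planned before. On day 18, 162 features were lower in zfp1 and higher in pax5, with medians of -0.61 and 0.35, and 103 of them were already lower in zfp1 on day 12. Their share of summed RPKM was 1.52 ± 0.0216% in unc22, 1.23 ± 0.0410% in zfp1 and 1.77 ± 0.0149% in pax5 libraries (SD, n = 4). The reverse pattern, higher in zfp1 and lower in pax5, held for 55 features, with medians of 0.43 and -0.58. The number expected of independent lists was not computed for either opposite pattern, so neither count is read as more than chance gives. In zfp1, 7 features fell at least 2-fold on all 3 days, and in pax5 134 did. Of these, 3 and 5 had no call in either other knockdown on any day. They were SMED30023708, SMED30012332 and SMED30034490 for zfp1 (log2 changes on day 18 of -1.11, -3.42 and -1.19), and SMED30010453, SMED30021619, SMED30018410, SMED30015916 and SMED30002026 for pax5 (-3.85, -2.75, -1.37, -1.55 and -1.63). For sox8 no feature met this description.

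The 98 features that rose at least 2-fold in zfp1 on day 18 made up 0.669 ± 0.347% of summed RPKM there and 0.171 ± 0.0257% in unc22 (SD, n = 4). By replicate the zfp1 libraries stood at 0.466%, 0.541%, 1.19% and 0.481%, so replicate 3 was far above the rest. Without replicate 3, 86 features rose at least 2-fold, of which 82 were among the 98. On day 12, 26 of the 98 were already called higher, and none was called in sox8 on day 18, where their median change was 0.04. Only 13 of all 22667 tested features were called higher in sox8 on that day, so the lack of calls says little about the 98. The 8 features that first fell at least 2-fold in zfp1 on day 6 had a zfp1 median of -1.30 on that day, and 4 of them were also called lower in sox8. On day 6, 2 of the 8 fell at least 2-fold in both sox8 and pax5 as well.

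Counts of calls were compared with those from other splits of the same libraries into groups of the same sizes, each split counted once and the real one included. For these results 1 of 35 splits, the real one, gave as many calls, which argues against chance. It is the smallest share that this test can give, so chance is not excluded. A technical difference between the groups of libraries is not addressed by it. In zfp1 against unc22 the real and the next highest counts were 308 and 12 on day 6, 2979 and 406 on day 12, and 5449 and 1648 on day 18. For sox8 they were 65 and 1 on day 12, and 173 and 4 on day 18. In pax5 they were 1161 and 94, 1418 and 1, and 1691 and 8 on days 6, 12 and 18. On day 18 they were 5197 and 1586 for zfp1 against sox8, 5414 and 1655 for zfp1 against pax5, and 1338 and 9 for sox8 against pax5. In unc22 over time they were 4074 and 6 to day 12, and 8677 and 1890 to day 18.

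For the total count of sox8 calls on day 6 chance could not be excluded. In 3 of 35 splits at least the real 175 features were called, and the highest other split called 1180. That split puts sox8 replicates 1, 2 and 3 with unc22 replicate 4, and its size points to a structure of these libraries. It keeps most of the real contrast, which without sox8 replicate 4 alone had 1144 calls, so the knockdown effect may be part of it. Some of the falls recurred in separate libraries. Of the 90 features lower on day 6, 28 (31.1%) were also lower on day 12, against 0.218 expected of independent lists. Of the 29 that fell at least 2-fold, 20 did so again. This argues against chance for the falls that recurred, but most of the 90 were not called lower on day 12. For the differences between day 18 and day 6, 100 splits were drawn. At least the real count came up in 3 of 100 for zfp1 (3412, highest other 3797). For pax5 it did so in 4 of 100 (452, highest other 569). These highest splits left the day 18 groups whole, so they kept the day 18 effect and were not free of the knockdown. With such splits among those drawn, these shares do not settle whether chance could give the counts. For sox8 at least the real count came up in 6 of 100 (7, highest other 537), so chance could not be excluded.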
